A study of Homo sapiens with 9 samples.

How the data were processed

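MicroRNAs were measured in 9 RNA samples of human breast cancer cells on 1-colour Agilent microarrays, 1 array per sample. The 3 groups of 3 arrays were MCF7 cells kept for 3 days without oestrogen (MCF7 without E2), MCF7 cells in 1 nM oestradiol (MCF7 with E2), and LTED cells, an MCF7 derivative kept long term without oestrogen. MCF7 is an established oestrogen receptor-positive line. Groups and replicate numbers came from the sample titles. The labels call the replicates separate RNA extractions and do not say that they came from separate cultures, so p-values measure only the spread between these extractions, which may be technical.

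The deposited scanner files were written by Agilent Feature Extraction 10.7.3.1, per the file headers, and hold spot intensity values that were background-subtracted but not normalized between arrays. Each array carried 53880 spots other than controls, for 3523 probes of 1347 miRNAs, of which 1205 were human and 142 viral. The authors also deposited a table of log2 values with 9 columns and 1368 entries. Its name and header call it quantile-normalized, and no header states its scale. Set against the scanner files over 163 miRNAs, each column correlated with an array of its own group at r of 0.995 or more on a log2 scale of the software's total gene signal. Its lowest value, -3.32, was the log2 of 0.1, the value the software gives an undetected miRNA. Column medians lay between -3.32 and -3.09. Whether further steps were applied to that table is not given in the sources used here. Its columns carry letters in place of replicate numbers.

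Control spots and outlier spots were left out, and the spots of a probe were averaged. A probe counted as detected on an array when at least a share of 0.5 of its kept spots were well above background. Each array was divided by its own 75th percentile over the 243 probes detected on all 9 arrays. Probes of 1 miRNA were averaged on the linear scale, so the brighter probe weighs more. A floor of 0.0337 of the scaled signal (log2 of -4.89) was then set, from the 1st percentile of detected probes, and log2 was taken. A miRNA was tested when detected on all 3 arrays of at least 1 group, which left 197 miRNAs, 190 of them human and 7 viral. Of these, 13 lay at the floor on all 9 arrays because the mean over their probes was under it. They kept their place in the tested set, gave no call, and lowered the prior degrees of freedom from 1.82 to 0.658. A miRNA at the floor understates a fold. Where no array of a group was well above background, the difference is given as a bound, taken on each of those arrays against the higher of the floor and the lowest detected signal of that array.

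Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 9 arrays, no trend, 6 residual degrees of freedom) with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. A moderated F-test compared the 3 groups. Of 31 miRNA lists, 16 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over 48 tests. Fry and camera with an estimated correlation were alternatives. Fry tests whether a list's members move one way on balance and does not compare the list with other miRNAs. Hairpins renamed since the lists were written were matched by their newer names. Tests, lists, alternatives and the rule for named miRNAs were fixed before the data were examined, except where the closing section says otherwise. Per contrast the rule took up to 8 miRNAs with the largest fold in each direction among calls whose groups did not overlap, up to 4 members of each list past its test, and a panel of miRNAs. The study's later interest in miR-23b was known, so this miRNA and its cluster are not independent evidence.

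The fit was tested on simulated data with each miRNA's real mean over all arrays and its real spread, 40 changed miRNAs among 197 and 50 simulated sets. The simulated noise was independent between arrays and miRNAs and no floor was set, so the shares found need not hold for the real arrays. For LTED against MCF7 without E2, 79.6% of changes of 1 log2 unit and 51.3% of changes of 0.5 were recovered, and 5.73% of calls were false. For LTED against MCF7 with E2 these were 76.8%, 55.1% and 5.62%, and for the oestradiol contrast 80.0%, 52.8% and 5.14%.

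Arrays with the same replicate number were compared through their deviations from the group means. For LTED and MCF7 with E2 the correlations were 0.493, 0.172 and 0.399, so by the criterion of 0.1 the numbers were taken to pair these arrays. The titles only number the replicates, and LTED replicate 2 correlated best with MCF7 with E2 replicate 1, so this pairing is uncertain. Deviations within a group sum to 0, and in both groups replicates 1 and 2 were near-identical and replicate 3 stood apart. These correlations are therefore not separate matches, and the criterion was easily met. The other contrasts did not meet the criterion. All arrays but LTED replicate 3 shared 1 slide, so the slide as a block equals the fit without that array. Alternatives changed the scaling, background correction, summary per miRNA, filter, floor, variance model, samples and blocks, and left out each array. Between 256 and 373 of the 3523 probes were detected per array. The 75th percentile over all probes, used as 1 alternative scaling, therefore lies among undetected probes, near background. Background correction by normexp with an offset of 50 used spot medians, since the files hold no spot means. Signals of near-identical miRNAs can mix by cross-hybridisation, so members of a family in a list need not be separate evidence. No coordinates are given, because the gene table at hand (GRCh38.p14) and the array annotation (GRCh37) differ in build; that table served only to find neighbouring hairpins. The number of arrays limits the precision.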

Results

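Global miRNA profiles were compared between oestrogen receptor-positive MCF7 breast cancer cells, with and without oestradiol, and LTED cells, a derivative used as a model of resistance to oestrogen deprivation. Each group had 3 arrays. Between 151 and 213 miRNAs were detected per array, and 145 were detected on all 9. MCF7 without E2 replicate 2 was the dimmest array, with 151 miRNAs detected and a log10 labelling spike-in signal of 2.87, against 3.17 to 3.26 on the other arrays. MCF7 with E2 replicate 3 carried high signals of GC-rich probes, with a median log2 signal of -2.01 against -3.77 and -3.65 on the other arrays of its group. Replicates 1 and 2 differed by an SD of 0.111 log2 units in LTED and 0.107 in MCF7 with E2, while all other replicate pairs differed by 0.273 to 0.545. All signals are log2 scaled values given as mean ± SD.

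The comparison of LTED with MCF7 without E2, both without oestrogen, asks what distinguishes the derivative from its short-term deprived parent. The largest differences were in miR-196a-5p, encoded within the HOX clusters, and miR-30a-5p. MiR-196a-5p stood at 0.81 ± 0.18 (SD, n = 3) in LTED and at the floor of -4.89 on all 3 MCF7 without E2 arrays, on 1 of which a probe was well above background, and its difference was 2.90 to 8.74 log2 units over the alternatives. MiR-30a-5p stood at -0.14 ± 0.09 (SD, n = 3) in LTED and also at the floor in the parent, where it was well above background on 2 of 3 arrays, and its difference was 2.12 to 7.31 over the alternatives. MiR-27b-3p was higher in LTED by 2.12 log2 units (SE 0.05, limma adjusted p = 2.07e-07) and miR-23b-3p by 2.04 (SE 0.05, limma adjusted p = 2.79e-07). Their near-identical relatives moved the other way: miR-23a-3p fell by 1.05 log2 units and miR-27a-3p by 0.85. Interest in miR-23b was known beforehand, so miR-23b and its cluster are not independent evidence; miR-27a-3p and let-7c-5p are named here after their values were seen.

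MiR-24-3p, which hairpins of both the miR-23a and the miR-23b cluster yield, rose by 1.01 log2 units. Of the 7 tested members of the miR-23, miR-27 and miR-24 list, 4 were higher, 2 lower and 1 did not pass, and the list as a whole did not pass (camera adjusted p = 0.341). MiR-99a-5p (1.61 log2 units), miR-125b-5p (1.71) and let-7c-5p (0.87) were all higher in LTED. In the list of the miR-99, let-7 and miR-125 clusters 3 of 7 members were higher and 1 was lower, with a median of -0.07 and a mean of 0.50 log2 units, and the list did not pass (camera adjusted p = 0.497). The let-7 family, known for repressing growth-promoting genes such as RAS, had 3 of 9 members higher and 3 lower, or 4 and 3 when adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.766).

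The miR-30 family rose as a list, with 6 of 7 tested members higher and none lower (camera adjusted p = 0.00143; adjusted p = 0.211 with an estimated correlation). The remaining member, miR-30e-3p, lay at the floor on all arrays. MiR-30c-5p was higher by 1.60 log2 units and miR-30d-5p by 0.68, and miR-30a-3p was at least 2.30-fold higher against the floor used here. The difference of miR-30a-3p was 0 to 7.06 log2 units over the alternatives, and its call ended with normexp and the floor times 4. The miR-181 family rose with 3 of 3 members (camera adjusted p = 0.0420; adjusted p = 0.486 with an estimated correlation), among them miR-181b-5p by 1.21 and miR-181a-5p by 1.10 log2 units. The miR-200 family, which maintains the epithelial state by repressing ZEB1 and ZEB2, fell with 4 of 5 members (camera adjusted p = 0.00852; adjusted p = 0.486 with an estimated correlation). MiR-200a-3p fell by 0.85 log2 units, miR-200b-3p by 0.59, miR-200c-3p by 0.49 and miR-141-3p by 0.42. The calls of miR-141-3p and miR-200b-3p ended under 7 and 6 alternatives. With the 75th percentile over all probes the list adjusted p became 0.0947 for the miR-200 family and 0.0937 for the miR-181 family, and with quantile normalization that of the miR-181 family was 0.109. With the replicate block it was 0.0690 for the miR-181 family, though the replicate numbers did not pair these groups. Adjusted over each list alone, 6 members of the miR-30 family, 3 of the miR-181 family and 5 of the miR-200 family passed. Signals of near-identical members can mix by cross-hybridisation, which was not tested for these families. In both LTED contrasts their members need not be separate evidence.

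Among the other lower miRNAs, miR-29a-3p fell by 1.48 log2 units (SE 0.12, limma adjusted p = 0.000121) and miR-29b-3p by 1.30. MiR-203a-3p, miR-342-5p, miR-140-3p, miR-96-5p and miR-140-5p fell by 1.08, 0.99, 0.99, 0.94 and 0.87 log2 units. With the floor times 4 the differences of miR-342-5p and miR-140-3p were 0 and that of miR-140-5p was -0.13, and these 3 calls also ended with normexp. MiR-21-5p, an abundant oncogenic miRNA, fell by 0.82. Quantile normalization sets the difference of miR-21-5p from both MCF7 groups to 0, since it holds the same rank, next below miR-720, on all 9 arrays. MiR-342-3p fell by 0.87, while miR-26a-5p and the hypoxia-induced miR-210-3p were higher by 0.38 and 0.42. The call of miR-26a-5p ended under 11 of 27 alternatives, with a difference as low as 0.031 log2 units. MiR-375, miR-17-5p, miR-18a-5p and miR-193b-3p did not pass, with differences of -0.08, 0.09, 0.19 and 0.36 log2 units.

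In all, 66 of 197 miRNAs differed between LTED and MCF7 without E2 (limma adjusted p under 0.05), 43 higher and 23 lower, and 13 and 4 of these differed by 2-fold or more. The groups did not overlap for any of the 66, nor for 86 of all tested miRNAs, where chance gives 10%. The count was 32 with the 75th percentile over all probes, 29 with normexp and 43 with the near-identical arrays averaged. Quantile normalization gave 55 calls with 25 higher, so the share of higher calls was 45.5% in place of 65.2%.

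**Figure D1:**
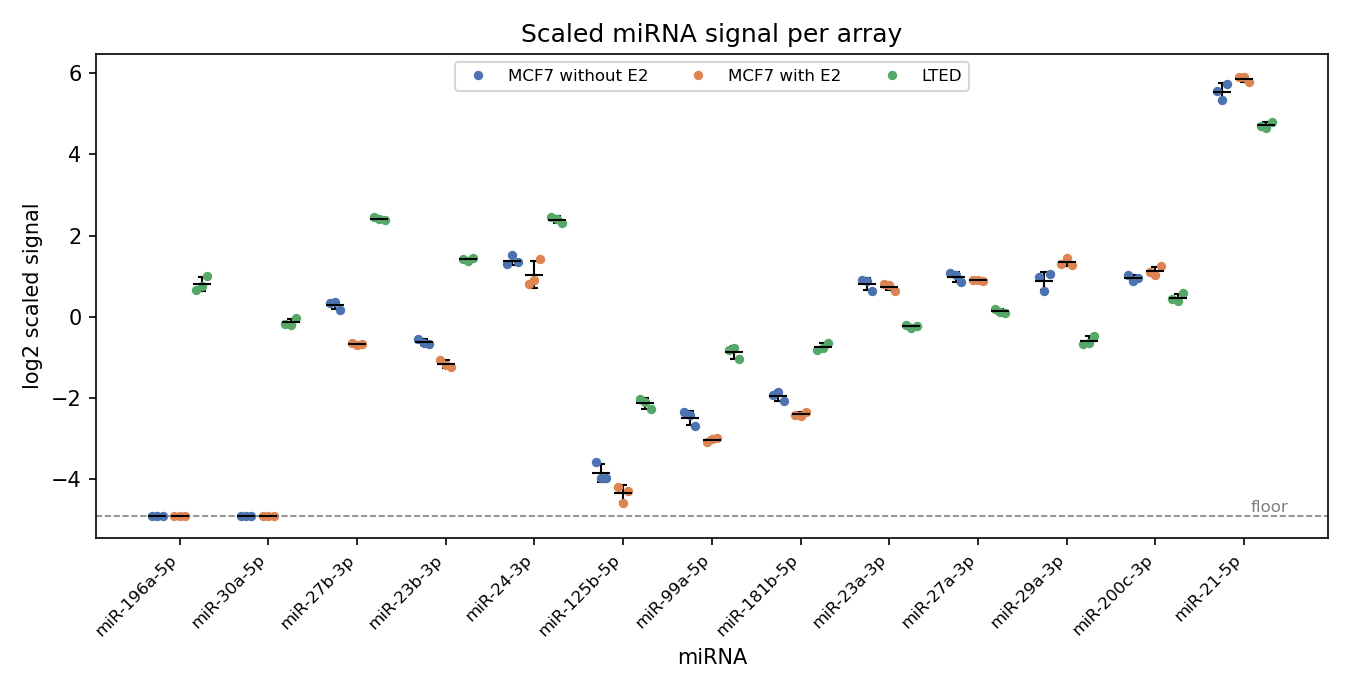
Log2 scaled signal (vertical axis) of 13 miRNAs (horizontal axis) on each array of the 3 groups, as points, with the mean as a bar and the SD as error bars (n = 3); the dashed line is the floor. MiR-196a-5p and miR-30a-5p lay at the floor of -4.89 on all MCF7 arrays, and miR-27b-3p and miR-23b-3p were higher in LTED while miR-23a-3p and miR-27a-3p were lower.

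The comparison of LTED with MCF7 in oestradiol differs in both the cells and the medium. The same miRNAs led it. MiR-196a-5p was at least 50.7-fold higher in LTED, and miR-30a-5p was at least 26.4-fold higher, against the floor used here. Over the alternatives their differences were 3.09 to 8.76 and 2.31 to 10.49 log2 units, all called, with the lowest under normexp. MiR-27b-3p was higher by 3.09 log2 units (SE 0.05, limma adjusted p = 1.72e-08), miR-23b-3p by 2.58, miR-125b-5p by 2.22 and miR-99a-5p by 2.15. MiR-149-5p, a member of the GC-rich list, was 1.66 above the floor, at which it lay on all 3 MCF7 with E2 arrays, and its difference was 0 to 2.85 over the alternatives. MiR-21-3p fell by 2.18 log2 units with the largest error of the named miRNAs (SE 0.49, limma adjusted p = 0.0113), and its adjusted p was 0.107 with the near-identical arrays averaged. MiR-29a-3p fell by 1.93, miR-29b-3p by 1.76, miR-140-3p by 1.17, miR-21-5p by 1.13 and miR-1260b by 1.04. MiR-1260b belongs to the list of miRNAs that overlap other small RNAs, of which 6 of 11 members were lower, also when adjusted over the list alone, while the list did not pass (camera adjusted p = 0.0703) except with the 75th percentile over all probes (adjusted p = 0.0117). The herpesviral hsv2-miR-H25 also passed, at -1.16 log2 units (SE 0.37, limma adjusted p = 0.0442). Its adjusted p was 0.128 with the near-identical arrays averaged, and the 7 tested viral miRNAs were all high on MCF7 with E2 replicate 3.

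By list, the miR-30 family rose again with 6 of 7 members (camera adjusted p = 0.00143; adjusted p = 0.211 with an estimated correlation), and the miR-200 family fell with 5 of 5 members (camera adjusted p = 0.00905; adjusted p = 0.486 with an estimated correlation). The list of the miR-193 and miR-365 clusters rose with 4 of 4 members (camera adjusted p = 0.0304; adjusted p = 0.482 with an estimated correlation), among them miR-193a-3p by 1.15 and miR-365a-3p by 0.54 log2 units. MiR-193b-3p, higher by 0.51, had an adjusted p of 0.0736 with the replicate block. The miR-181 family rose with 2 of 3 members (camera adjusted p = 0.0465, or 0.486 with an estimated correlation). Camera with the replicate block gave an adjusted p of 0.0690. With the 75th percentile over all probes the adjusted p was 0.0937 for the miR-200 family, 0.0937 for the list of the miR-193 and miR-365 clusters and 0.0947 for the miR-181 family, and with quantile normalization it was 0.114 for the last. Adjusted over each list alone, 6 members of the miR-30 family, 5 of the miR-200 family, 4 of the miR-193 and miR-365 clusters and 3 of the miR-181 family passed. MiR-375, a miRNA of luminal breast cells, was higher by 0.49 log2 units, miR-26a-5p by 0.59 and miR-24-3p by 1.35, while miR-342-3p fell by 0.53 and miR-23a-3p by 0.98. MiR-210-3p, miR-17-5p and miR-18a-5p did not pass, with differences of -0.05, 0.11 and 0.12.

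In all, 85 of 197 miRNAs differed (limma adjusted p under 0.05), 48 higher and 37 lower, and the groups did not overlap for 84 of them. The count was 38 with the 75th percentile over all probes, 47 with normexp and 53 with the near-identical arrays averaged. Quantile normalization gave 66 calls with 30 higher, so the share of higher calls was 45.5% in place of 56.5%. LTED differed in the same direction from both parental groups for 38 higher and 19 lower miRNAs. Independent lists of these sizes share 10.5 and 4.32, and part of the excess may come from the shared LTED arrays. Simulated groups without any difference shared 0 calls. Few calls can arise where nothing differs, so this 0 does not gauge the effect of the shared arrays.

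The response of the parental line to oestradiol was smaller. MiR-27b-3p fell in oestradiol by 0.96 log2 units (SE 0.05, limma adjusted p = 0.000114), from 0.29 ± 0.10 to -0.67 ± 0.03 (SD, n = 3). MiR-23b-3p fell by 0.54 (SE 0.05, limma adjusted p = 0.00326), while miR-23a-3p and miR-27a-3p differed by -0.07 and -0.09 and did not pass. MiR-375, miR-99a-5p and miR-181b-5p fell by 0.57, 0.55 and 0.45, calls that ended under 15, 19 and 14 of 27 alternatives. MiR-210-3p was higher by 0.47, miR-1274a, which overlaps a transfer RNA, by 0.58 and miR-550a-3p by 0.34, the last near the floor. These calls ended under 15, 16 and 21 alternatives, and miR-550a-3p also changed sign under 1.

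5 lists passed in this contrast, all with small differences and none with an estimated correlation. The list of the miR-99, let-7 and miR-125 clusters was lower with 1 of 7 members past its own test, or 5 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.482 with an estimated correlation), with let-7c-5p at -0.40 and miR-125b-5p at -0.51 log2 units, neither past its test over all miRNAs. The miR-23, miR-27 and miR-24 list (camera adjusted p = 0.00378; 2 of 7 members), the let-7 family (camera adjusted p = 0.00408; 0 of 9 members) and the luminal list (camera adjusted p = 0.0104; 1 of 6 members, miR-375) were also lower. Their adjusted p with an estimated correlation was 0.482, 0.486 and 0.482. MiRNAs that overlap other small RNAs were higher as a list (camera adjusted p = 0.00408; adjusted p = 0.541 with an estimated correlation), with miR-1274a past its own test among 11 members, and miR-4286 at 0.38 and miR-1260a at 0.42 not past theirs. Adjusted over each list alone, 2 members of the miR-23, miR-27 and miR-24 list, 3 of the let-7 family, 1 of the luminal list and 2 of the small RNA list passed. With the 75th percentile over all probes the adjusted p was 0.0662 for the let-7 family and 0.0937 for the miR-23, miR-27 and miR-24 list, and with fry it was 0.0834 for the let-7 family and 0.0803 for the small RNA list.

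Only 8 of 197 miRNAs passed (limma adjusted p under 0.05), 3 higher and 5 lower, and 35 had an unadjusted p under 0.05. The count was 0 with the 75th percentile over all probes, 1 with normexp or the software's total signal, 3 with quantile normalization and 17 without the dim array and the array with high GC-rich probes, of which 3 were among the 8. It was 2 without LTED replicate 1 or 2 or MCF7 with E2 replicate 1 or 2, 4 without MCF7 without E2 replicate 1 and 5 without its replicate 3, and none of the 8 passed under every alternative.

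Across the 3 groups the F-test called 80 miRNAs (limma adjusted p under 0.05). Across miRNAs, which are not independent replicates, the differences of LTED and of oestradiol-treated MCF7 from the shared MCF7 without E2 arrays correlated at r = -0.108. Simulated groups without any difference that share those arrays gave a mean of 0.501 (0.258 to 0.698). LTED differed widely, which alone brings such a correlation nearer to 0, so these correlations cannot be set against each other. The simulation also took miRNAs as independent. The covariance was -0.0274 against 0.0306 simulated, a difference of -0.0580. The correlation was 0.0477 without MCF7 without E2 replicate 3 and 0.0456 with the deposited table. Of the 8 miRNAs called in oestradiol, 5 were also called in LTED against MCF7 without E2, where independent lists share 2.68 and the contrasts share the MCF7 without E2 arrays, 4 of them with the opposite sign and miR-210-3p with the same sign.

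**Figure D2:**
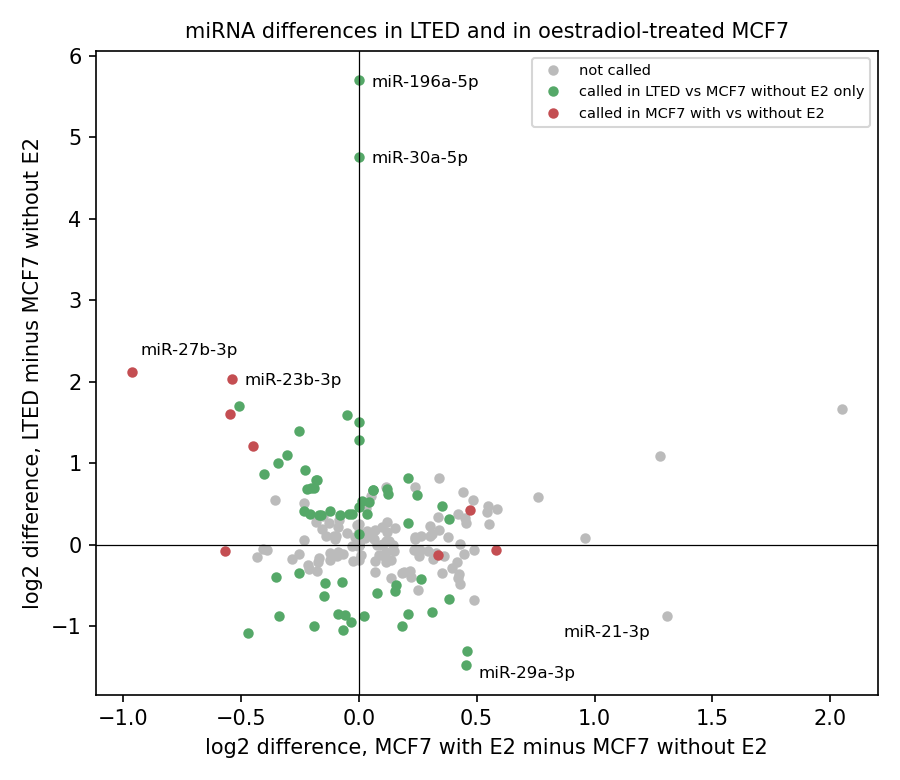
Log2 difference of LTED from MCF7 without E2 (vertical axis) against that of MCF7 with E2 from MCF7 without E2 (horizontal axis), 1 point per tested miRNA, coloured by the contrast that called it. MiR-27b-3p and miR-23b-3p were higher in LTED and lower in oestradiol, and the correlation across the 197 miRNAs was -0.108.

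Markers of other cell types were sought. None of the measured members of the blood cell (11), endothelial (2), fibroblast and smooth muscle (9), basal and mesenchymal (12) and muscle (4) lists was detected often enough to be tested. Of the nerve list 1 of 6 was tested, miR-128-3p, higher by 0.27 log2 units in LTED against MCF7 without E2 (limma adjusted p = 0.0377). MiR-221-3p, miR-222-3p, miR-190b and miR-10a-5p were well above background on 0 arrays, and miR-205-5p on 1.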

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

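Alternatives that average near-identical arrays, leave out 2 doubtful arrays, leave out GC-rich and viral probes, or leave out miRNAs constant at the floor were chosen after seeing the data. Of the named calls, 13 of 29 in LTED against MCF7 without E2, 15 of 32 in LTED against MCF7 with E2 and 0 of 8 in the oestradiol contrast passed under every alternative that gave them a value; miR-196a-5p, miR-30a-5p, miR-27b-3p, miR-23b-3p, miR-23a-3p, miR-24-3p and miR-29a-3p did so in both LTED contrasts. In LTED against MCF7 without E2 the calls lost most often were miR-26a-5p (11 alternatives), miR-181a-3p (8 and 1 change of sign), miR-141-3p (7), miR-200b-3p (6) and miR-203a-3p (4). In LTED against MCF7 with E2 they were hsv2-miR-H25 (12), miR-193b-3p (11), miR-375 (5) and miR-342-3p (5). In oestradiol calls were lost under 1 alternative for miR-27b-3p, 5 for miR-23b-3p and 14 (miR-181b-5p) to 21 (miR-550a-3p) for the other 6. Near the floor, miR-140-3p (both LTED contrasts), miR-140-5p, miR-342-5p, miR-30a-3p, miR-149-5p and miR-193a-5p lost their calls with normexp and the floor times 4. The cause was not tested unless stated.

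Counts for LTED against MCF7 without E2, LTED against MCF7 with E2, the oestradiol contrast and the F-test were 32, 38, 0 and 31 with the 75th percentile over all probes, 29, 47, 1 and 37 with normexp, and 43, 53, 2 and 42 with near-identical arrays averaged, which leaves fewer samples. For the oestradiol contrast alone, the count was 3 with quantile normalization, 3 with the deposited table, 1 with total gene signal, 4 with the floor times 4, 3 with only the 2 groups, 4 with the slide row as a block and 17 with the 2 doubtful arrays left out. Leaving out each array gave 54 to 74, 68 to 84, 2 to 12 and 61 to 87 calls. The deposited table gave 59 calls with 21 higher for LTED against MCF7 without E2 and 73 with 29 higher for LTED against MCF7 with E2. With no filter, 1138 of 1347 miRNAs lay at the floor on all arrays; limma called all of these on rounding error, so they were left out, and the other 209 gave 63, 83, 7 and 79 calls. Without the 13 constant miRNAs of the tested set they were 65, 84, 7 and 79.

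With the replicate block the counts were 66, 80, 5 and 70, of which 2 of the 5 were among the original 8 calls, and 10 lists passed. Same-numbered correlations were 0.541, -0.0507 and 0.373 for LTED with MCF7 without E2 and 0.784, -0.106 and 0.711 for the MCF7 groups. The block left the correlation across miRNAs at -0.108. For LTED against MCF7 with E2 it ended the call of miR-193b-3p and of the miR-181 list among the named miRNAs and lists, and no other. It also ended that list's call for LTED against MCF7 without E2.

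Of 48 list tests, 12 passed, against 0 with an estimated correlation, 25 with fry and 6 with the 75th percentile over all probes. The correlation across miRNAs was 0.0456 with the deposited table and -0.192 to 0.0477 with each array left out, above 0 only without MCF7 without E2 replicate 3. 2 called miRNAs changed sign, with normexp: miR-181a-3p in LTED against MCF7 without E2 (-0.0033) and miR-550a-3p in oestradiol (-0.12). The other sign changes were in miRNAs not called in the contrast concerned. In LTED against MCF7 without E2, miR-17-5p was -0.058 with the 75th percentile over all probes, -0.043 with quantile normalization and -0.063 with the deposited table. In LTED against MCF7 with E2, miR-18a-5p was -0.021 with the floor times 4, -0.077 with near-identical arrays averaged and -0.042 to 0.39 with each array left out, and miR-210-3p was 0.018 with normexp. In oestradiol, miR-23a-3p was 0.022 with the 2 doubtful arrays left out, and miR-141-3p was -0.052 with quantile normalization and -0.098 with the deposited table. There miR-17-5p was 0.012 with the slide row as a block, 0.049 with near-identical arrays averaged and -0.15 to 0.068 with each array left out. MiR-18a-5p was -0.056 with the 75th percentile over all probes, -0.046 with normexp, -0.008 with the deposited table, -0.36 with the 2 doubtful arrays left out and -0.20 to 0.23 with each array left out.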

Other observations

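Some tests were chosen after their results were seen. These were the tests of weaker labelling, of probe-driven signal, of cross-hybridisation, of the miR-23b hairpin cluster and of a wrong label on an array. The neighbour test without 17 of its pairs and the count over all splits for the F-test were also among them.

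In LTED against MCF7 with E2, 2 of 3 tested members of the miR-29 family, miR-29a-3p and miR-29b-3p, were lower, and the list did not pass (camera adjusted p = 0.191). The remaining member, miR-29c-3p, named after its value was seen, was at 0.38 log2 units (limma adjusted p = 0.0497). Its difference stayed above 0 under 27 alternatives, from 0.076 to 0.44, but passed under only 13 of them, with adjusted p from 0.0122 to 0.759, so its call is not firm. The cluster of miR-183, miR-96 and miR-182 had 2 of 4 members lower in LTED against MCF7 without E2 and did not pass (camera adjusted p = 0.140). Its other members, miR-182-5p and miR-183-3p, lay at the floor on all arrays and could not differ. The miR-17 clusters had 2 of 14 lower and none higher, with a median of 0.03 and a mean of -0.05 log2 units (camera adjusted p = 0.394). Of these miR-25-5p and miR-93-3p lay at the floor on all arrays.

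MiR-23b-3p and miR-27b-3p were higher and miR-23a-3p and miR-27a-3p lower in LTED. Cross-hybridisation alone would carry the relatives the same way, and miR-23a-3p instead differed by -1.05. That fall is part of the pattern and was known beforehand, so it is no independent test. It shows only that cross-hybridisation alone does not give the opposite signs, and partial mixing of the signals stays open. The scaling is argued against, since the smallest of the 4 differences was 0.82 in its own direction over 4 scalings. A candidate explanation is a higher output of the miR-23b, miR-27b and miR-24-1 hairpins, which neighbour each other in the gene table. This stays open: miR-24-1-5p was 2.44-fold higher, but it was detected on 2 of 3 MCF7 without E2 arrays at the floor, so the bound that the test called for does not exist there (against MCF7 with E2 it was at least 2.38-fold).

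GC-rich and viral probes were high on MCF7 with E2 replicate 3, by a median of 1.18 log2 units over 15 GC-rich miRNAs and 1.03 over 7 viral ones. Replicate 3 had the highest median of both sets in the other groups too (GC-rich -2.55 against -2.86 and -2.73 in LTED, -2.71 against -3.96 and -2.91 in MCF7 without E2), so a cause shared by the arrays of that number was not tested and stays open. On the MCF7 with E2 array the labelling spike-in differed from the mean of the other arrays of its group by -0.042 log10 units, which argues against weaker labelling. The other arrays of that group differed from MCF7 without E2 by -0.25 over the GC-rich list, where a response to oestradiol would raise them. The MCF7 without E2 mean includes replicates 2 and 3, whose GC-rich medians were themselves above that of replicate 1, so this difference cannot decide on such a response. Signal that needs no matching miRNA stays open: the 7 viral miRNAs, which human cells without these viruses do not make, were all higher, but they are part of the pattern and do not test it.

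MiR-21-3p was high on 2 of 3 MCF7 with E2 arrays. Both of its probes dropped on replicate 3, by at least 1.70 log2 units, which argues against a faulty probe. On that array miR-27b-3p and miR-23b-3p lay nearer to the other MCF7 with E2 arrays than to MCF7 without E2, by at least 0.50 log2 units. Both are calls of the oestradiol contrast, which used this array's label. Their choice thus favoured this outcome, so it cannot decide on a wrong label. MiR-21-5p dropped by 0.13, so miR-21 as a whole did not move alike. No cause that was tested was shown to account for the pattern, and a wrong label stays open. Replicates 1 and 2 of this group are the near-identical arrays.

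MiRNAs of hairpins within 10000 bases of each other (29 pairs in the GRCh38.p14 gene table, brightest arm each) were tested for changing together in LTED against MCF7 without E2. Their mean absolute gap was 0.25 log2 units against 0.66 in shuffled pairs (one-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Without 17 pairs of related miRNAs or of miR-23b and miR-27b, the gap was 0.42 against 0.66 over 12 pairs (permutation p = 0.122). Cross-hybridisation between related miRNAs therefore stays open, and the hypothesis is not settled.

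With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; the real split was the 1 of 10 with as many calls in each contrast. LTED against MCF7 without E2 gave 66 calls and the highest other split 0, LTED against MCF7 with E2 85 and 0, and the oestradiol contrast 8 and 2. For the F-test, 1 of 100 splits drawn from 280, the real one, gave as many as 80 calls, which argues against a random division of these extractions. The splits treat the extractions as independent, so chance differences between cultures are not excluded if the replicates are technical. The highest other drawn split gave 64. Over all 280 splits the real one was still the only 1 with as many calls, but the highest other gave 78. The 9 other splits that kept the LTED arrays together gave 59 to 78 calls and those that parted them at most 2, so the count rests on LTED standing apart and hardly on the division of the MCF7 arrays.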
